A study of Mus musculus with 12 samples.

How the data were processed

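Whole TA muscle was flash-frozen and extracted with TRIzol, and the amplified and labelled RNA was measured on arrays of the Affymetrix type Mouse Gene 1.0 ST, per the labels and the design text of the series. There were 12 arrays in 4 groups of 3. Per the submitters' processing notes the authors used Affymetrix Power Tools and RMA, a method that corrects background, equalises the distributions of the arrays and summarises probes into 1 value per transcript cluster (a set of probes for 1 gene). Versions, the genome build and the annotation are not given in the sources used here. The deposited values are in the unit intensity, on a linear scale from 4.65 to 21512.5, with 24922 transcript clusters and 0 missing values. RMA draws extreme values together and can compress differences of weakly expressed genes. No array was identical to another.

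Values were taken to log2 with no pseudocount and no filter on dim clusters. Gene names came from the gene table of the array, which lists 1 symbol for 21425 clusters, several for 1399 and has no entry for 2098; only clusters with 1 symbol were used. The Entrez numbers of 21347 clusters matched a RefSeq table of the GRCm38.p6 assembly, which was used for names only, and 0 symbols were changed by it. Of the genes, 921 had several clusters and were represented by the cluster with the highest mean over the 12 arrays, which left 19752 genes. Among the genes named for the size or p of their change these were Ccdc141 with 5 clusters and Snora3, Tent5a, Fbxo31 and Stxbp4 with 2 each. Genes named only as list members were not looked up for this. Of 33 genes with several clusters that were called for the mean effect, 2 had clusters of opposite sign, against 0 of 32 at day 4. Genes without a cluster of their own, such as Areg, were not analysed here. No genomic positions are given, since no build is named for the values.

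Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 4 group means and 1 estimate of the spread (8 residual and 7.1 prior degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 19752 were called, all tests being two-sided. The comparisons were AREG against PBS at day 4 and at day 8, the mean and the difference of these effects, and the PBS groups at day 8 against day 4. The comparisons, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, as were the tests unless said otherwise. Standard errors (SE) are those of the fit and n is 3 per group. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1, so none was used for single genes.

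Gene lists for cell types, fibre states, metabolism and signalling, 35 with 736 members of which 684 were measured, were tested with limma's camera at a preset correlation between genes of 0.01. Each call is given with the result of the correlation estimated per list, and fry was run beside it. Some genes are in more than 1 list, and bulk muscle expresses many members of the lists in several of its cell types. For lists that passed, the median and the direction of the test had the same sign in all 5 comparisons; median and mean differed in sign in 2 lists at day 4, 4 at day 8, 2 for the mean effect, 4 for the difference and 2 between the PBS groups. The correlation between the AREG effects was set against relabelled arrays within each setting. For comparisons that share PBS arrays, groups without effects were simulated from shuffled residuals, 1000 times for correlations and 100 times for shared calls, the latter added after the results had been seen.

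Where at least 20 genes passed, the 10 largest rises and the 10 largest falls were named, leaving out ribosomal, predicted, Rik and olfactory receptor genes. Otherwise all genes that passed were named, with up to 12 per direction with the smallest p among genes above the median level, with an absolute log2 change of at least 0.58 and no overlap between the groups. To these were added Foxp3, Egfr and up to 4 members with the smallest p of each list described.

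Whether replicate numbers pair AREG and PBS arrays was checked on residuals. At day 4 arrays of the same number correlated at 0.558, 0.201 and 0.511, and at day 8 at -0.198, 0.123 and -0.003. Arrays of different number at day 4 ranged from -0.486 to 0.270, the latter between AREG replicate 2 and PBS replicate 3. Numbers 1 and 3 therefore went together at day 4, number 2 did not stand out, and no number did so at day 8. The replicate 1 arrays of day 4 also had the narrowest interquartile ranges (2.19 and 2.37), so the values do not settle whether the numbers mark pairs. No pairing was used for the values reported, and a fit with the replicate number as a block was an alternative. The other alternatives were a fit of the 6 arrays of a setting alone, eBayes with trend and robust options, array quality weights, a filter at the median level, quantile normalisation, centring on medians, a pseudocount of 32, the mean of a gene's clusters, all clusters, and leaving out each array in turn. Leaving out both arrays with the lowest quality weights was added after the data had been seen.

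The fit was tested on simulated data with 200 changed genes per comparison among 19752, at the spread of these arrays. Of 100 genes with a log2 change of 1 it recovered 99% at day 4, 97% at day 8, 100% for the mean effect, 89% for the difference and 98% between the PBS groups. False calls numbered 11, 7, 6, 10 and 13 in the same order. Simulated genes varied independently and with the same spread on every array, unlike the real ones, so these shares do not carry over. In the real arrays C1qtnf3 fell by 1.32 at day 8 and was not called (adjusted p = 0.599, limma). Arrays carry no count depth; the median SE of a log2 difference was 0.136 within a day, 0.0964 for the mean effect and 0.193 for the difference. Replicate 1 of the day 4 AREG group had the narrowest interquartile range (2.19 log2 units, against 2.37 to 2.72 in the others) and the lowest quality weight (0.167), and replicate 3 of the day 8 AREG group the next lowest weight (0.321). The highest weights were 7.43 for replicate 2 of the day 8 AREG group and 5.52 for replicate 3 of the day 4 AREG group.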

Results

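RNA from whole tibialis anterior (TA) muscle of C57BL/6 mice, 8 weeks old, was measured on 12 microarrays. The muscle had been injured with cardiotoxin, a snake venom protein that kills muscle fibres and starts a round of regeneration, on day 0. All mice received diphtheria toxin, which per the design depletes regulatory T (Treg) cells only in mice that carry the diphtheria toxin receptor under control of Foxp3 (Foxp3-DTR+). Mice were given amphiregulin (AREG), a growth factor that binds the epidermal growth factor receptor, or phosphate-buffered saline (PBS) as its vehicle. The arrays fell into 4 groups of 3: AREG and PBS at day 4 in mice without the receptor (Foxp3-DTR-, Treg cells present), and AREG and PBS at day 8 in Foxp3-DTR+ mice (Treg-depleted). Day and genotype therefore changed together, and any difference between processing batches could not be told apart from them. The median intensity per array lay between 134 and 143, and 19752 genes were tested. The labels do not say that each array came from a separate animal, so p-values measure the spread between samples, and the number of arrays limits the precision.

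The first question was what AREG did to injured muscle at day 4, with Treg cells present. Among the genes called lower were genes of macrophages, of the extracellular matrix, of dividing cells and of newly formed fibres, and among those called higher genes of fat storage. At the level of lists, 15 passed with a preset correlation between genes and 0 of them with an estimated correlation. Gpnmb, a glycoprotein of phagocytic repair macrophages, fell by 2.00 ± 0.34 on the log2 scale (SE, n = 3 per group, a 4.00-fold change, adjusted p = 0.0198, limma). Cthrc1, a secreted protein of activated matrix-producing cells, fell by 1.62 ± 0.19 (adjusted p = 0.00279). Chac1, an enzyme that degrades glutathione and is induced by the stress factor ATF4, had the largest rise, 1.72 ± 0.32 (adjusted p = 0.0198). In all, 573 genes passed an adjusted p of 0.05, of which 156 were higher and 417 lower with AREG (27.2% higher). At an unadjusted p under 0.05 there were 3363 genes, against 988 that chance would give, and 112 of the called genes differed by at least 1 on the log2 scale.

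Among macrophage genes, the pan-macrophage list fell at day 4, with a median log2 change of -1.21 over its 20 measured members, all 20 of them lower (adjusted p = 0.18 with an estimated correlation). Of these members 13 fell over all genes tested and 19 when adjusted over the list alone. Lgals3 (galectin-3) fell by 1.59 ± 0.29, the scavenger receptor Msr1 by 1.23 ± 0.24, the lysosomal protein Cd68 by 1.42 ± 0.28 and the high-affinity IgG receptor Fcgr1 by 0.99 ± 0.20 on the log2 scale. In each AREG array at day 4 the mean of this list lay below that of each PBS array of the same day. The repair macrophage list fell as well, with a median of -0.68 over 23 members (adjusted p = 0.18 with an estimated correlation). In that list 6 members fell over all genes and 13 adjusted over the list alone, where 1 rose. Besides Gpnmb these included the lipid carrier Fabp5 (-1.20 ± 0.21), the phagocyte receptor Trem2 (-1.15 ± 0.22) and Apoe (-0.92 ± 0.17). The inflammatory monocyte list fell, with a median of -0.46 over 20 members (adjusted p = 0.18 with an estimated correlation), and 6 of its members fell over all genes and 9 adjusted over the list alone. The chemokines Ccl3 and Ccl2, which attract leukocytes, fell by 1.67 ± 0.37 and by 0.80 ± 0.20 on the log2 scale. The largest falls outside the lists were those of Atp6v0d2 (-2.11 ± 0.53), a subunit of the proton pump of lysosomes, and Ms4a6d (-1.75 ± 0.26). Mmp12, the macrophage elastase, fell by 1.52 ± 0.28 on the log2 scale, and the lysosomal protease Ctss and Glipr1 by 1.56 ± 0.38 and 1.55 ± 0.33.

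The extracellular matrix and fibrosis list fell at day 4, with a median of -0.80 over 29 members (adjusted p = 0.192 with an estimated correlation). Of its members 10 fell over all genes tested and 20 adjusted over the list alone. Thrombospondin-2 (Thbs2) fell by 1.16 ± 0.13, the matrix glycoprotein Tnc (tenascin-C) by 1.55 ± 0.30, the metalloprotease Adam12 by 0.87 ± 0.15 and Ltbp2, which binds elastic microfibrils, by 0.80 ± 0.12 on the log2 scale. The proliferation list fell, with all 39 members lower and a median of -0.56 (adjusted p = 0.18 with an estimated correlation). Here 14 members fell over all genes and 31 adjusted over the list alone, among them the ribonucleotide reductase subunit Rrm2 (-1.04 ± 0.18) and the mitotic genes Plk1 (-0.90 ± 0.15), Prc1 (-0.78 ± 0.14) and Kif2c (-0.72 ± 0.13).

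Genes of newly forming muscle were also lower with AREG at day 4. The regenerating fibre list fell, with a median of -0.90 over 18 members (adjusted p = 0.18 with an estimated correlation), and 9 of its members fell over all genes tested and 14 adjusted over the list alone. Mymk (myomaker), a membrane protein needed for myoblast fusion, fell by 1.31 ± 0.23, the embryonic acetylcholine receptor subunit Chrng by 1.28 ± 0.22, the adhesion molecule Ncam1 by 1.01 ± 0.18 and brain-type creatine kinase Ckb by 0.94 ± 0.17 on the log2 scale. The satellite cell and myoblast list fell with a smaller median, -0.13 over 23 members (adjusted p = 0.216 with an estimated correlation). In it Mymk, Myog (-1.10 ± 0.21), the transcription factor of myoblast differentiation, and the laminin receptor subunit Itga7 (-0.71 ± 0.15) fell over all genes, and 8 members fell adjusted over the list alone.

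The lists that rose with AREG at day 4 belong to fat storage, oxidative metabolism, mature fibres and vessels. The adipocyte list rose, with all 17 members higher and a median of 0.49 (adjusted p = 0.18 with an estimated correlation). The triglyceride synthesis enzyme Dgat2 rose by 0.77 ± 0.17, and the lipid droplet proteins Cidec and Plin1 rose by 0.73 ± 0.16 and 0.64 ± 0.16, which made 3 members over all genes and 12 adjusted over the list alone. The oxidative phosphorylation list rose as a group, with 44 of 44 members higher and a median of 0.25 (adjusted p = 0.272 with an estimated correlation), although limma called 0 members over all genes and 0 adjusted over the list alone. The fatty acid oxidation list rose by a median of 0.30 over 22 members (adjusted p = 0.272 with an estimated correlation). Its member Ppargc1a, a coactivator of mitochondrial biogenesis, rose by 0.65 ± 0.11 (adjusted p = 0.0198), and 4 members rose adjusted over the list alone. The mature fast fibre list rose by a median of 0.20 over 30 members (adjusted p = 0.266 with an estimated correlation). Tcap, a protein of the sarcomeric Z-disc, rose by 0.63 ± 0.13, the only member called over all genes, and 8 members rose adjusted over the list alone. The endothelial list rose by a median of 0.25 over 24 members with 0 called (adjusted p = 0.515 with an estimated correlation), also 0 adjusted over the list alone. Outside the lists, Klhl33 rose by 1.27 ± 0.18, Timp4, an inhibitor of metalloproteases, by 1.12 ± 0.26, the complement component C7 by 1.09 ± 0.22 and Ces1d, a carboxylesterase, by 1.08 ± 0.28. Sh3rf2 (1.04 ± 0.23), Nt5c1a (0.99 ± 0.18), Plcd4 (0.98 ± 0.23), Agbl1 (0.94 ± 0.21) and the adipocyte galectin Lgals12 (0.93 ± 0.19) completed the largest rises.

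Interferon and lymphocyte lists gave these values at day 4. The type I interferon response list fell, with all 22 members lower and a median of -0.42 (adjusted p = 0.192 with an estimated correlation). Oasl2 (-0.83 ± 0.19) and Rtp4 (-0.76 ± 0.17) fell over all genes and 11 members adjusted over the list alone. The MHC class II list fell with a median of -0.44 over 10 members with 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.383 with an estimated correlation). The neutrophil list fell with a median of -0.08 over 20 members with 0 called over all genes and 2 adjusted over the list alone (adjusted p = 0.515 with an estimated correlation). The interferon-gamma, T cell, NK and Treg lists did not pass the list test, with medians of -0.11, -0.01, -0.0003 and -0.03. Only 3 of 18 T cell, 3 of 14 NK, 5 of 21 Treg and 0 of 20 neutrophil members lay above the median level of all genes. At such low levels small medians do not show that these cells were unchanged. The list of immediate genes downstream of the epidermal growth factor receptor and ERK did not pass either, with a median of -0.04 over 34 members. In that list Atf3 (-0.77 ± 0.15) and Egr2 (-0.58 ± 0.14) fell over all genes, 2 members fell and 1 rose adjusted over the list alone, and Erbb3, a receptor of the same family, fell by 0.65 ± 0.14.

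In camera with the preset correlation 15 of the 35 lists passed at day 4, 5 higher and 10 lower. With an estimated correlation 0 of them held. In the rotation test fry, which asks whether a list's genes move one way without reference to other genes, 13 of the 35 lists passed. Among these were 12 of the 15. The groups of 4395 genes (22.2%) did not overlap, against 10% by chance. The number of called genes rested on single arrays: without replicate 3, 1 or 2 of the AREG group 9, 15 or 308 genes passed, and without replicate 2 or 1 of the PBS group 9 or 228. Through the shared spread, leaving out replicate 1, 2 or 3 of the day 8 AREG group gave 927, 302 or 1336 genes, and replicate 1 of the day 8 PBS group 312. With the replicate number as a block, which the values at day 4 bore out for numbers 1 and 3 only, 914 genes passed (305 higher, 609 lower). After a repeated quantile normalisation 877 passed (363 higher, 514 lower). With array quality weights 5305 passed (2785 higher, 2520 lower), so the excess of falls did not hold in that fit. There the AREG mean rested mainly on replicate 3 (weight 5.52, against 0.936 and 0.167 for the other AREG arrays). Of 49 genes that passed at day 4 and were followed through the alternatives, Cthrc1 and Thbs2 passed in all 22 settings. Those followed were genes named for the size of their change and leading members of lists that passed.

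**Figure D1:**
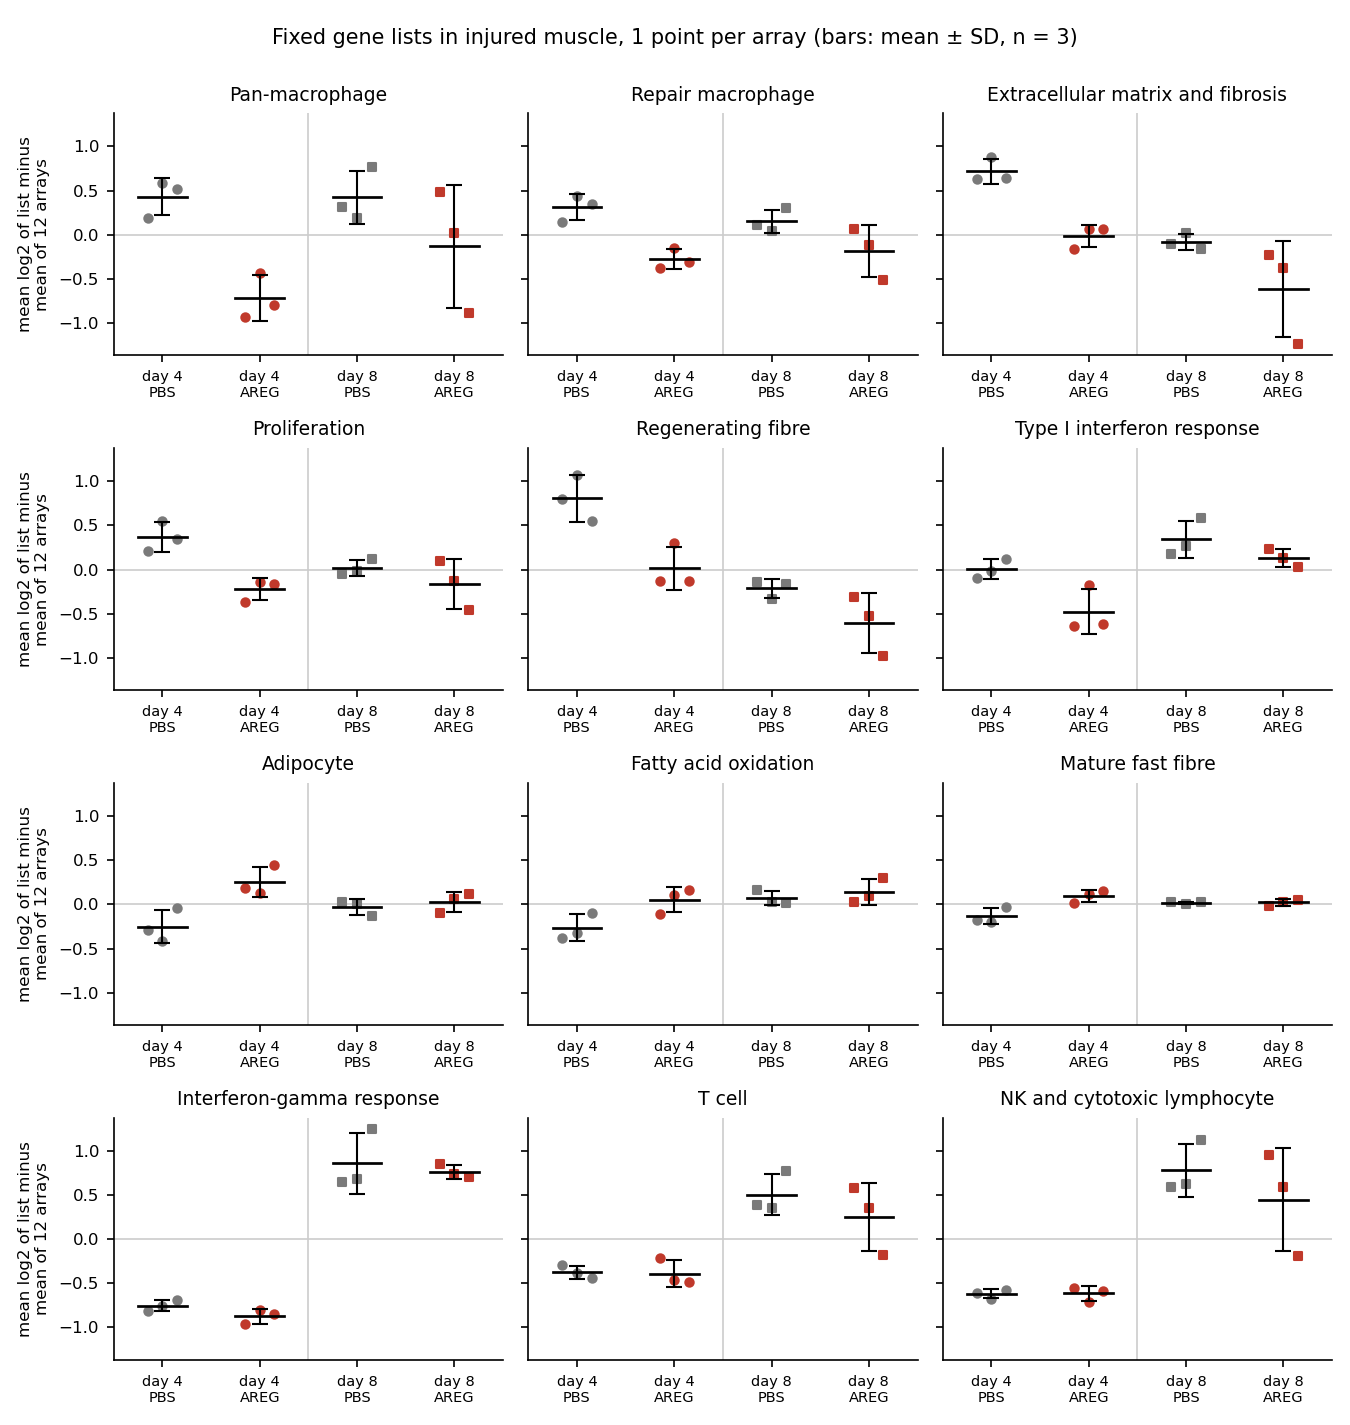
Mean log2 level of 12 fixed gene lists in each array, minus the mean over the 12 arrays (vertical axis, log2), by group; circles stand for day 4 and squares for day 8, grey for PBS and red for AREG, and bars give the mean and SD of the 3 arrays. The pan-macrophage list lies lower in the AREG arrays than in the PBS arrays at day 4, and at day 8 replicate 3 of the AREG group lies below the other AREG arrays in the macrophage, matrix and lymphocyte lists.

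The next question was what AREG did at day 8 in Treg-depleted mice. Mmp12 was the 1 gene that passed, and it fell by 2.06 ± 0.28 on the log2 scale (SE, n = 3 per group, a 4.16-fold change, adjusted p = 0.0482, limma). Of the lists that passed, the matrix and pan-macrophage lists had the medians farthest below 0, and no list passed in the other direction. Among genes at or above the median level 9 lists passed, 3 of them higher. With an estimated correlation 0 lists held (adjusted p = 0.537 with an estimated correlation for each of them). At an unadjusted p under 0.05 there were 1506 genes, against 988 by chance. The call of Mmp12 was lost in 17 of 22 alternatives, the replicate block among them (0 genes), and its adjusted p ranged from 7.89e-05 to 0.59. With array quality weights 1192 genes passed (457 higher, 735 lower).

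The extracellular matrix and fibrosis list fell at day 8 with a median of -0.59, with 28 of its 29 members lower and 0 called over all genes by limma, against 15 adjusted over the list alone (adjusted p = 0.537 with an estimated correlation). Tnc (-1.01 ± 0.30), the metalloprotease inhibitor Timp1 (-0.87 ± 0.25), Thbs2 (-0.53 ± 0.13) and Thbs4 (-0.53 ± 0.16) had the smallest p in this list. The pan-macrophage list fell with a median of -0.57 with 20 of 20 members lower (adjusted p = 0.537 with an estimated correlation), none of them past the test over all genes or adjusted over the list alone. In the regenerating fibre list, which fell with a median of -0.41, 5 members fell adjusted over the list alone, and in the repair macrophage list, which fell with a median of -0.35, it was 2 (adjusted p = 0.537 with an estimated correlation for each). The proliferation, MHC class II and inflammatory monocyte lists fell with medians of -0.16, -0.44 and -0.26, and the dendritic cell, NK and T cell lists with medians of -0.24, -0.42 and -0.20. The type I interferon list (-0.17), the fibro-adipogenic progenitor list (-0.23), the Treg list (-0.11), the tendon list (-0.13), the glycolysis list (-0.11) and the immediate EGFR-ERK list (-0.08) completed the 16 that passed. Each of these 12 lists also had an adjusted p of 0.537 with an estimated correlation, and limma called 0 of their members over all genes. Adjusted over the list alone, 1 member of the Treg list and 2 of the EGFR-ERK list fell. The oxidative phosphorylation (-0.006), mature fast fibre (-0.006), interferon-gamma (-0.02) and adipocyte (0.15) lists did not pass.

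Of the 16 lists, 0 held with an estimated correlation and 0 in fry. Replicate 3 of the AREG group carried part of the list result, since 8 lists passed without it, and the NK and fibro-adipogenic progenitor lists then changed the direction of their test. Other genes with no overlap between the groups, none of them past the threshold, are given as values only, with unadjusted p of up to 0.0579 (Snora31). Among those lower with AREG were Rcn3 (-0.95 ± 0.16, adjusted p = 0.239), the secreted Wnt modulator Sfrp1 (-0.64 ± 0.12), C1qtnf3 (-1.32 ± 0.26), the ERK phosphatase Dusp6 (-0.68 ± 0.15) and Ccdc141 (-1.20 ± 0.27), the last 4 at an adjusted p of 0.599. Others were the collagen hydroxylase P4ha3 (-1.01 ± 0.24), Apoe (-0.69 ± 0.17), Shc1 (-0.61 ± 0.14), Mxra8 (-0.59 ± 0.14), Pagr1a (-0.63 ± 0.16) and Tent5a (-0.62 ± 0.15). Those higher with AREG included the small nucleolar RNAs Snora3 (0.99 ± 0.29), Snora31 (0.75 ± 0.37), Snora74a (0.61 ± 0.26) and Snord33 (0.60 ± 0.17), the translation repressor Eif4ebp1 (0.62 ± 0.21) and the slow myosin light chain Myl3 (0.62 ± 0.29). Vaultrc5 (0.73 ± 0.25), Ctxn3 (0.68 ± 0.25), Ppp1r27 (0.65 ± 0.25) and Mir133a-2 (0.63 ± 0.20) were the remaining ones.

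**Figure D2:**
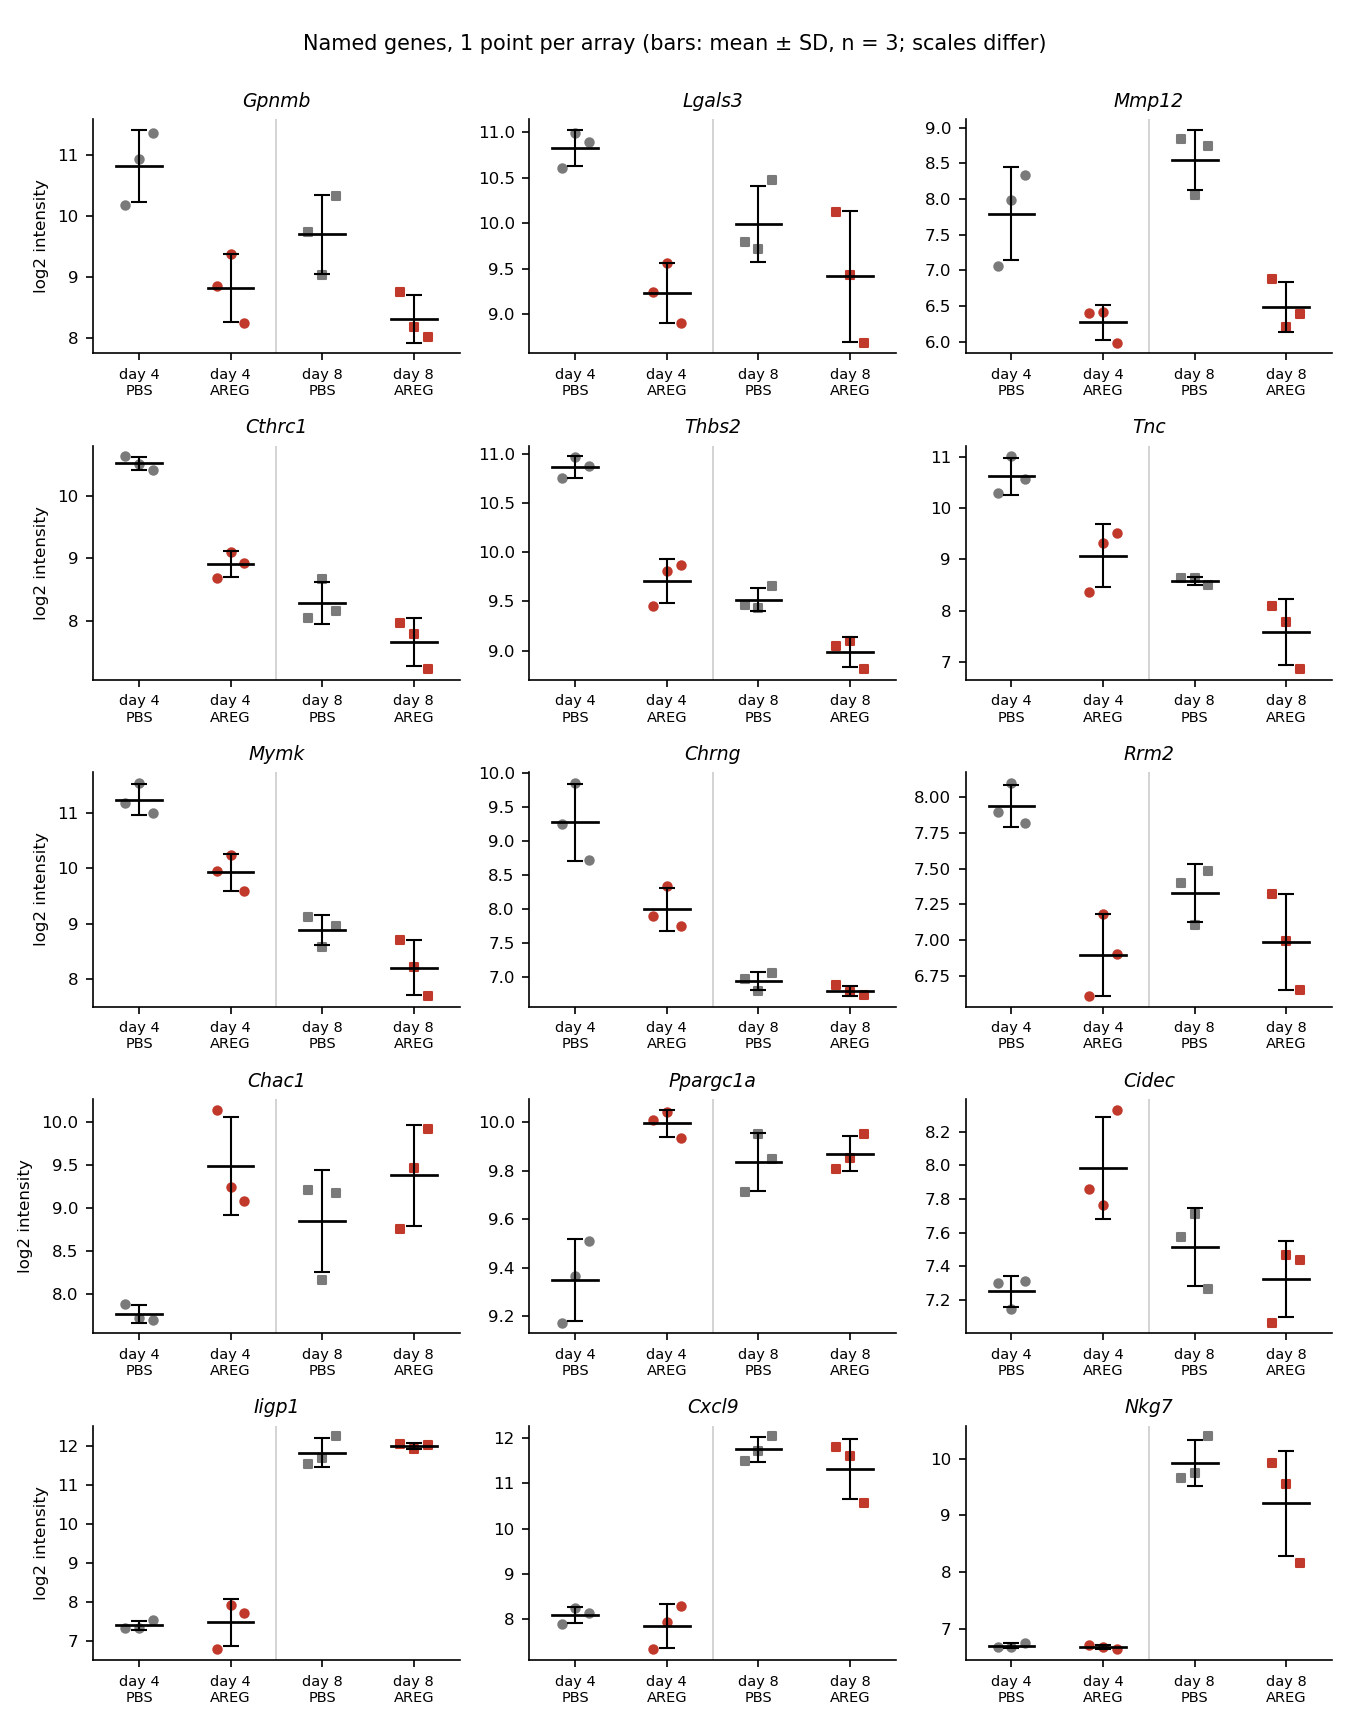
Log2 intensity of 15 named genes in each array (vertical axis, with a scale of its own in each panel), by group; circles stand for day 4 and squares for day 8, grey for PBS and red for AREG, and bars give the mean and SD of the 3 arrays. Gpnmb, Mmp12, Cthrc1 and Thbs2 lie lower with AREG at both days, while Iigp1, Cxcl9 and Nkg7 separate day 8 from day 4 whatever the treatment.

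The AREG effects of both settings were also averaged, a mean that 1 setting can carry alone. Macrophage and matrix genes were among those called: Mmp12 fell by 1.79 ± 0.20, Gpnmb by 1.69 ± 0.24 and Thbs2 by 0.85 ± 0.09 on the log2 scale (SE from 6 arrays per treatment, limma; adjusted p = 0.00183, 0.00949 and 0.00183). Besides Mmp12 and Gpnmb, the largest mean falls were those of Atp6v0d2 (-2.02 ± 0.37), the interleukin-7 receptor Il7r (-1.47 ± 0.30), C1qtnf3 (-1.38 ± 0.19), Tnc (-1.28 ± 0.21), Mest (-1.20 ± 0.29), Ms4a6d (-1.18 ± 0.18), Ccdc141 (-1.17 ± 0.19) and P4ha3 (-1.16 ± 0.17). Chac1 rose by 1.12 ± 0.22, Myl3 by 0.84 ± 0.20, Timp4 by 0.84 ± 0.19 and the lipid droplet protein Plin4 by 0.64 ± 0.16. Fbxo31 (0.68 ± 0.18), Ppp1r1a (0.67 ± 0.14), Sh3rf2 (0.63 ± 0.16), Lncpint (0.62 ± 0.10), Wnk2 (0.62 ± 0.13) and neuronal nitric oxide synthase Nos1 (0.59 ± 0.14) made up the rest of the largest rises. Altogether 673 genes passed, 82 higher and 591 lower (12.2% higher), and 391 of them were also called at day 4.

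By list, the mean effect called 14 of 20 pan-macrophage genes lower (20 adjusted over the list alone, median -0.89) and 13 of 29 matrix genes (26 adjusted over the list alone, median -0.65). It called 14 of 39 proliferation genes (30 adjusted over the list alone, median -0.37) and 11 of 18 regenerating fibre genes lower (15 adjusted over the list alone, median -0.67). The adjusted p with an estimated correlation was 0.195 for each of these 4 lists. In the repair macrophage list 8 of 23 fell (14 adjusted over the list alone, median -0.47), and in the adipocyte list 2 of 17 rose (6 adjusted over the list alone, median 0.32), with an adjusted p of 0.195 and 0.198 with an estimated correlation. Dusp6 (-0.47 ± 0.11), Egr2 (-0.55 ± 0.10), Atf3 (-0.52 ± 0.11) and Fos (-0.37 ± 0.09) fell in the immediate EGFR-ERK list (5 members adjusted over the list alone, median -0.03, adjusted p = 0.402 with an estimated correlation). Of 35 lists 19 passed, 6 higher and 13 lower, 0 with an estimated correlation and 10 in fry. Without replicate 2 or 3 of the day 4 PBS group 34 or 442 genes passed, without replicate 1 or 3 of the day 4 AREG group 61 or 203, without replicate 1 or 2 of the day 8 AREG group 1488 or 414, and without replicate 1 or 3 of the day 8 PBS group 80 or 65. With the replicate number as a block 1104 passed (209 higher, 895 lower). With array quality weights 4902 passed, and the excess of falls was much smaller (2300 higher, 2602 lower). After a repeated quantile normalisation 715 genes passed, 199 higher and 516 lower.

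Whether the AREG effect differed between the settings was tested directly. Across genes the effects at day 4 and day 8 had a Pearson correlation of 0.498 and a Spearman correlation of 0.381. Genes are not independent replicates, so these values were set against 400 pairs of relabelled splits, which gave permutation p = 0.04 for Pearson and 0.08 for Spearman (2 relations computed, Benjamini-Hochberg adjusted 0.08 for each). The relabelling took no account of any pairing by replicate number. Without replicate 3 of the day 8 AREG group the Pearson value was 0.224 (permutation p = 0.27). Of the 417 genes that fell at day 4, 402 (96.4%) also lay lower at day 8, with a median of -0.80 at day 4 and -0.34 at day 8. Of the 156 that rose at day 4, 95 (60.9%) lay higher at day 8, with medians of 0.64 and 0.04. These shares were not set against relabelled arrays. Genes that vary together can share a sign as a block, so the shares are not a replication gene by gene.

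**Figure D3:**
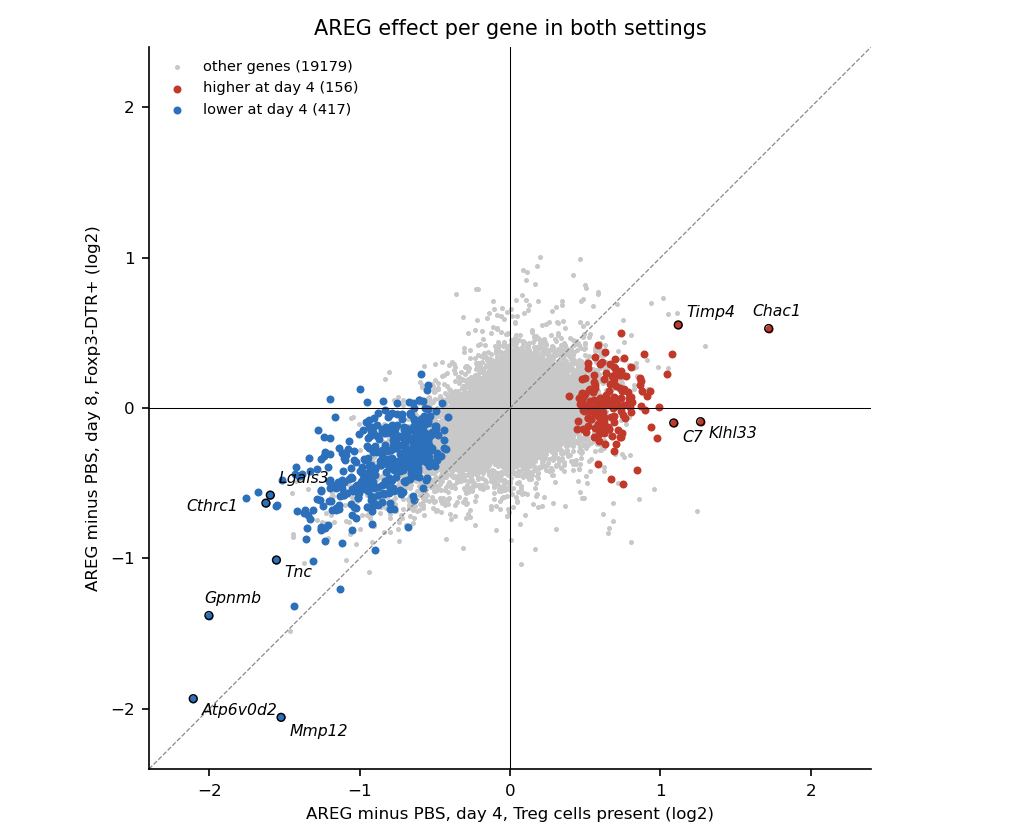
Log2 difference between AREG and PBS for each of 19752 genes at day 4 (horizontal axis) and at day 8 (vertical axis), with genes called higher (156, red) or lower (417, blue) at day 4 in colour and the line of equal effects dashed. Of the blue points 402 lie below 0 on the vertical axis, with Gpnmb, Atp6v0d2 and Mmp12 the farthest down.

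For the difference itself limma called 0 genes, with 1160 at an unadjusted p under 0.05 against 988 by chance and a smallest adjusted p of 0.426. With array quality weights 2232 genes passed (865 higher, 1367 lower), so the absence of calls depended on the fit. In that fit each AREG mean rested mainly on 1 array. Replicate 3 of the day 4 AREG group had a weight of 5.52, against 0.936 and 0.167 for the others. Replicate 2 of the day 8 AREG group had 7.43, against 0.583 and 0.321. Camera with the preset correlation called 20 lists, 10 in each direction, with 0 genes of any list past the test over all genes. Of these lists 0 held with an estimated correlation (smallest adjusted p = 0.445) and 0 in fry. Genes lower with AREG at day 4 and less so, or not, at day 8, given as values of the difference only, included the heme oxygenase Hmox1 (0.99 ± 0.19, adjusted p = 0.426), Chrng (1.13 ± 0.31), Nt5dc2 (1.04 ± 0.29), Tubb2b (0.99 ± 0.27), Cthrc1 (0.99 ± 0.27), Cd63 (0.89 ± 0.19), Plk1 (0.84 ± 0.21), Rps19 (0.82 ± 0.18), Rrad (0.82 ± 0.20), Ltbp2 (0.76 ± 0.17), Spsb1 (0.70 ± 0.18) and F13a1 (0.64 ± 0.17). Those higher with AREG at day 4 and less so, or lower, at day 8 included the lipid desaturase Scd1 (-1.46 ± 0.31), Slc37a4 (-1.44 ± 0.33), Klhl33 (-1.36 ± 0.26), Stxbp4 (-1.26 ± 0.21), Lrp2bp (-1.15 ± 0.23), Sgk1 (-1.01 ± 0.23), Abcd2 (-0.93 ± 0.22), Jak2 (-0.87 ± 0.17), Cntfr (-0.86 ± 0.18), Deptor (-0.83 ± 0.17), BC023105 (-0.83 ± 0.15) and Plpp7 (-0.78 ± 0.18).

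The PBS groups describe the settings in which AREG was given: Treg-depleted muscle at day 8 against muscle with Treg cells at day 4. Among the genes called higher at day 8 were genes induced by interferon-gamma and genes of cytotoxic lymphocytes, and among those called lower genes of newly formed fibres and matrix. Of the lists, only the interferon-gamma list held with an estimated correlation. Iigp1, an interferon-induced GTPase, rose by 4.42 ± 0.23 on the log2 scale (SE, n = 3 per group, a 21.4-fold change, adjusted p = 4.37e-08, limma). Cxcl9, a chemokine that attracts T cells, rose by 3.66 ± 0.28, the granule protein Nkg7 by 3.23 ± 0.32 and the inhibitory ligand Cd274 (PD-L1) by 2.81 ± 0.33. Peg10 had the largest fall (-2.55 ± 0.19), followed by Mymk (-2.35 ± 0.23), Chrng (-2.32 ± 0.22) and Cthrc1 (-2.24 ± 0.19). In all 463 genes passed, 236 higher and 227 lower, with 2585 at an unadjusted p under 0.05.

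The interferon-gamma response list rose by a median of 1.42, with 19 of 23 members called over all genes and 21 adjusted over the list alone, and this was the 1 list of the study that also held with an estimated correlation (adjusted p = 0.0101). Gbp4 (3.28 ± 0.25), Irgm1 (2.95 ± 0.24), Gbp2b (2.90 ± 0.31), Gbp7 (2.77 ± 0.32) and Gbp8 (2.67 ± 0.26), GTPases of the same response, were among the largest rises. The NK and cytotoxic lymphocyte list rose by a median of 1.19, with 10 of 14 members called over all genes and 13 adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). Ccl5 rose by 2.83 ± 0.37 and the protease granzyme B (Gzmb) by 2.36 ± 0.33. The T cell list rose by a median of 0.75, with 11 of 18 members called over all genes and 13 adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). Cd3g rose by 2.55 ± 0.32 and the CD8 co-receptor chains Cd8b1 and Cd8a by 1.82 ± 0.26 and 1.62 ± 0.25. The MHC class II list rose by a median of 1.11, with 6 of 10 members called over all genes and 6 adjusted over the list alone (adjusted p = 0.154 with an estimated correlation), among them H2-Ab1 (1.48 ± 0.30) and H2-Eb1 (1.42 ± 0.25). In the type I interferon list, median 0.27, 4 of 22 members rose over all genes and 8 adjusted over the list alone (adjusted p = 0.293 with an estimated correlation). The dendritic cell list rose by a median of 0.11, with the receptor Clec9a (1.48 ± 0.29) and the chemokine Ccl22 (0.81 ± 0.18) called over all genes, 3 higher and 1 lower adjusted over the list alone, and an adjusted p of 0.313 with an estimated correlation. Among genes at or above the median level the direction of its test turned (median 0.00557).

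The Treg list was higher in the depleted setting. It rose by a median of 0.17 over 21 members, with 4 called over all genes and 7 adjusted over the list alone (adjusted p = 0.154 with an estimated correlation). The members that rose, Icos (1.21 ± 0.20), Il2ra (0.99 ± 0.11), Klrg1 (0.92 ± 0.15) and Ctla4 (0.61 ± 0.12), are also made by activated conventional T cells. Foxp3 itself, the transcription factor that defines Treg cells, lay between 6.49 and 6.75 log2 units in all 12 arrays and differed by -0.02 ± 0.11 (adjusted p = 0.955). This level was near the 38.2nd percentile of all genes, so whole-muscle Foxp3 gave no measure of the depletion. Egfr, the AREG receptor, lay between 8.63 and 9.49 log2 units and passed in none of the comparisons. Areg was not analysed here, since no probe set named it alone.

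Among muscle and matrix genes, the regenerating fibre list was lower at day 8 than at day 4 under PBS and fell with a median of -1.06, with 9 of 18 members called over all genes and 13 adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). The embryonic troponin Tnnt2 fell by 1.88 ± 0.27 on the log2 scale, and Dclk1, Nt5dc2 and the tubulins Tubb2b and Tubb6 by 2.00 ± 0.24, 1.91 ± 0.20, 2.21 ± 0.19 and 1.80 ± 0.23. The matrix list fell with a median of -0.69, with 10 of 29 members called over all genes and 20 adjusted over the list alone (adjusted p = 0.154 with an estimated correlation), including Tnc (-2.04 ± 0.30), the collagen cross-linking enzyme Lox (-1.44 ± 0.20) and Thbs2 (-1.35 ± 0.13). The satellite cell and myoblast list fell with a median of -0.31 with 6 of 23 called (12 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation). The proliferation list fell with a median of -0.36 with 2 of 39 called (15 adjusted over the list alone, adjusted p = 0.299 with an estimated correlation). The neutrophil list fell with a median of -0.17 with only Mmp8 called (1 adjusted over the list alone, adjusted p = 0.305 with an estimated correlation). The oxidative phosphorylation list rose with a median of 0.29 with all 44 members higher and 2 called (12 adjusted over the list alone, adjusted p = 0.154 with an estimated correlation). The fatty acid oxidation list rose with a median of 0.32 with 2 of 22 called (8 adjusted over the list alone, adjusted p = 0.161 with an estimated correlation).

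In the same comparison the adipocyte list rose with a median of 0.26 and the mature fast fibre list with a median of 0.13, with 1 member called in each over all genes and adjusted over the list alone (Thrsp and Myh2; adjusted p = 0.305 and 0.299 with an estimated correlation). The endothelial list rose with a median of 0.13 and 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.527 with an estimated correlation). The pan-macrophage list did not pass, with a median of -0.05 and 0 of 20 members called. In the repair macrophage list, which did not pass either, Retnla, a marker of macrophages activated by interleukin-4, rose by 2.20 ± 0.27, while Stab1 (-1.05 ± 0.17), Trem2 (-1.05 ± 0.22) and Apoe (-0.71 ± 0.17) fell. In all 17 lists passed, 12 higher and 5 lower, and 13 of all lists passed in fry, with 11 of the 17 among them. Among genes at or above the median level 15 passed, 8 higher and 7 lower. The number of called genes was 283 or 209 without replicate 1 or 2 of the day 4 PBS group, 267, 277 or 241 without replicate 1, 2 or 3 of the day 8 PBS group, and 719 without replicate 3 of the day 8 AREG group. With the replicate number as a block it was 540, and with array quality weights 1649.

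Some genes that AREG lowered at day 4 were also lower at day 8 under PBS. Both comparisons called 133 genes lower and 19 higher, and 0 genes in opposite directions. Independent lists of these sizes would share 4.79 and 1.86 genes, a value that leaves out the shared arrays, and simulated groups without effects, which leave out the effects, shared 0 and 0. Cthrc1, Thbs2, Tnc, Mymk, Chrng and Myog were among the genes called lower in both. The comparisons share the 3 PBS arrays of day 4, which pushes such counts up, and these arrays were not divided between them. Across all genes the Pearson correlation was 0.409, against 0.473 from the shared arrays alone in simulations, so neither the overlap nor the correlation measures a shared effect.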

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

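The tests of array distributions, of the spread at day 8 and of the share of injured tissue were chosen only after the results had been seen, as were the counts of splits by pairs for the mean effect, and the test of the spread replaced an earlier ratio of SDs that had left it open; the test of shared PBS arrays and the counts over other splits of the arrays were chosen before. What drew attention here was a test of the difference between the AREG effects of the settings, in which 20 gene lists passed with a preset correlation between genes.

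Lists whose log2 value for AREG against PBS was less negative or more positive at day 8 than at day 4 (median difference; the pan-macrophage list, for one, was lower with AREG at both days and by less at day 8) were the pan-macrophage (0.590), regenerating fibre (0.466), proliferation (0.384), repair macrophage (0.285), type I interferon (0.276), muscle atrophy (0.252), satellite cell and myoblast (0.235), inflammatory monocyte (0.204), extracellular matrix (0.163) and neutrophil (0.100) lists. Those whose value was less positive or more negative at day 8 were the adipocyte (-0.407), NK and cytotoxic lymphocyte (-0.386), tendon (-0.341), glycolysis (-0.246), oxidative phosphorylation (-0.243), T cell (-0.197), fatty acid oxidation (-0.192), mature fast fibre (-0.166), endothelial (-0.159) and Treg (-0.0733) lists. With an estimated correlation 0 of the 20 held (smallest adjusted p = 0.445), and 0 in fry. Of 100 splits of the arrays, 10 gave as many lists, the real one included, with 23 the highest of the others, so chance is not excluded for this count. Without replicate 3 of the day 8 AREG group the T cell, NK and muscle atrophy lists changed the direction of their test.

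The first pattern is the 573 genes called for AREG at day 4 against 1 at day 8, a contrast that was not itself established, since limma called 0 genes for the difference (1160 at an unadjusted p under 0.05), although with array quality weights it called 2232, and 1192 at day 8. The narrow range of values in replicate 1 of the day 4 AREG group is argued against as its cause, since after quantile normalisation 877 genes passed, 551 of the 573 among them. Without that array the called genes had a median of 0.941 times their effect (quartiles 0.871 and 1.04). They had been called with the array included, so this value could hardly fall far and does not decide the question. The calls did depend on that array: without it 45 of the 49 called genes followed lost their call, and without replicate 3 it was 47. Faults of the array other than its range were not tested. A larger spread between arrays at day 8 is argued against as well: the fit used 1 spread per gene for both days, and with the spread of the day 4 arrays alone the day 8 effects gave 6 calls against 938 for the day 4 effects (the SD within groups at day 8 was 0.867 times that at day 4 over all genes and 1.14 times over the genes called at day 4). Some lists did vary more between AREG arrays at day 8. The SD of the matrix list mean was 0.547 at day 8 and 0.128 at day 4, and that of the pan-macrophage list 0.698 and 0.257. The type I interferon list went the other way (0.105 and 0.258). The sizes of the day 8 matrix and macrophage effects are therefore less certain. The design names day and Treg depletion, which change together and remain open as untested biological explanations.

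The second pattern is the opposite movement at day 4 of macrophage, matrix, proliferation and regenerating fibre lists (lower) and lists of metabolism and mature fibres (higher). Differences in the distributions of array values are argued against, since all 15 lists that passed kept their direction and call after quantile normalisation. A smaller share of injured tissue in the AREG samples may account for it and stays open. Among bright members the satellite cell list lay 1.10 above the pan-macrophage list (median -1.23, quartiles -1.36 and -0.994). Nearer to the latter lay the regenerating fibre (-0.917, quartiles -1.10 and -0.71), matrix (-0.801) and proliferation (-0.589) lists. Satellite cells are also present in uninjured muscle, and no uninjured arrays show what a smaller share of injured tissue would do. The biological alternative, that AREG changed the course of the injury response, was not tested apart from it.

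The third pattern is that AREG at day 4 and day 8 against day 4 under PBS moved genes the same way. The 3 PBS arrays of day 4 shared by both comparisons stay open as a candidate cause: the covariance across genes was 0.0293 against 0.0137 in simulations without group effects, an excess of 0.0157, and 63 of 1000 simulations gave as much, while the correlation, 0.409, lay below the simulated 0.473. The simulations leave out any pairing of AREG and PBS arrays at day 4, so the simulated values are only a rough guide. A biological link, such as an injury response that AREG brings forward, was not tested, and the 3 PBS arrays were not divided between the comparisons.

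For the counts of genes, 3 against 3 arrays make 10 splits, too few for a share under 0.05. At day 4 the real split gave 573 genes and the highest other 1, so that 1 of 10 splits reached the real count. Among the 4 splits that part all 3 pairs of replicate numbers at day 4, the highest other gave 0. At day 8 the real split gave 1 gene and the highest other 1 (2 of 10 splits), and between the PBS groups 463 and 0 (1 of 10). For the mean effect, 2 of 100 splits gave at least the real 673 genes, a share under 0.05. This share rests on the real day 4 arms, which 12 of the splits kept, so it does not exclude chance. The highest other, 1056, kept the real day 4 arms with other day 8 arms, and 2 of the 12 splits that kept them reached the real count. Of the 44 splits that part all 3 pairs of replicate numbers at day 4, the same 2 did, and among splits without the real day 4 arms the highest gave 2. For the difference the real split gave 0 genes, so all 100 splits gave as many, with 1014 the highest other; that split kept the real day 4 arms and exchanged 2 arrays of each day 8 arm. Its count points to a structure of the samples, which can be the AREG effects themselves, since with all day 8 arms exchanged the difference becomes the sum of both effects and called 673 genes. Splits without the real day 4 arms gave 0 genes at most for the difference.

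For the counts of lists, the real split at day 4 gave 15 and the highest other 15 (2 of 10 splits), at day 8 16 and 19 (6 of 10), and between the PBS groups 17 and 19 (3 of 10), again too few splits for a share under 0.05. For the mean effect 23 of 100 splits gave at least the real 19 lists, with 22 the highest other, so chance is not excluded.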

How the results depend on the processing

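Of the alternatives below, leaving out both arrays of the lowest quality weight was chosen after the data had been seen; all others were planned. With 3 arrays per group and 8 residual degrees of freedom, gene counts moved more than effects. The genes followed through the alternatives were those named for the size or p of their change and leading members of lists that passed. Other named genes, such as Atf3, Runx1 and Erbb3 at day 4, were not followed. No followed gene changed direction in any comparison. Among followed genes that were called, the call held in all settings for 2 of 49 at day 4, 10 of 60 for the mean effect, 38 of 58 between the PBS groups and 0 of 1 at day 8. Where no cause is given for a change, the cause was not tested.

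Numbers of called genes follow for day 4 (573), day 8 (1), the mean effect (673), the difference (0) and the PBS groups (463). Fitted on the 6 arrays of a setting, day 4 gave 938 and day 8 0. With array quality weights the counts were 5305, 1192, 4902, 2232 and 1649. In each AREG group 1 array carried most of the weight (5.52 at day 4 and 7.43 at day 8), so these counts rest mainly on it. Higher and lower calls were then 2785 and 2520 at day 4, against 156 and 417 without weights. For the mean effect they were 2300 and 2602, against 82 and 591. Quantile normalisation gave 877 at day 4 and a pseudocount of 32 gave 358, while centring on medians gave 444 for the mean effect. At day 8 the count was 0 with the trend and robust options, the replicate block, the filter at the median level, quantile normalisation, centring, the pseudocount, the mean of a gene's clusters and all clusters. With both arrays of lowest weight out, day 4 gave 1394, day 8 0, the mean effect 348 and the PBS groups 1057.

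The replicate number as a block gave 914 genes at day 4, where numbers 1 and 3 of AREG and PBS arrays went together, and 0 at day 8, where none did. It gave 1104 for the mean effect, 0 for the difference and 540 between the PBS groups. Without pairs the values were 573, 1, 673, 0 and 463.

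Leaving out 1 array at a time, with a group of 2 assumed to vary like the others, gave 9 to 1336 genes at day 4, 0 to 1 at day 8, 34 to 1488 for the mean effect, 0 for the difference in all 12, and 209 to 719 between the PBS groups. The arrays that moved the day 4 count by more than 1.5 times were replicates 1, 2 and 3 of the day 4 AREG group (15, 308 and 9), 1 and 2 of the day 4 PBS group (228 and 9), 1, 2 and 3 of the day 8 AREG group (927, 302 and 1336) and 1 of the day 8 PBS group (312). For the mean effect they were replicates 1 and 3 of the day 4 AREG group (61 and 203), 2 and 3 of the day 4 PBS group (34 and 442), 1 and 2 of the day 8 AREG group (1488 and 414) and 1 and 3 of the day 8 PBS group (80 and 65). Between the PBS groups they were replicates 1 and 2 of day 4 (283 and 209), 1, 2 and 3 of day 8 (267, 277 and 241) and 3 of the day 8 AREG group (719). At day 8 the count was 0 without any of replicates 1, 2 and 3 of the day 4 AREG group, 2 of the day 4 PBS group, 2 and 3 of the day 8 AREG group, and 1 and 3 of the day 8 PBS group.

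Numbers of lists were 15, 16, 19, 20 and 17 in the same order. With an estimated correlation 0, 0, 0, 0 and 1 passed, and with fry 0 at day 8, 10 for the mean effect and 0 for the difference. At day 8 the filter at the median level left 9 (3 higher, 6 lower) and both arrays out 4. Leaving out 1 array gave 14 to 16 lists at day 4, 8 to 19 at day 8, 16 to 22 for the mean effect, 14 to 21 for the difference and 17 to 20 between the PBS groups; the 8 came without replicate 3 of the day 8 AREG group. The direction of the list test turned in few cases, given here with the list's median. With the filter, which left 15 lists between the PBS groups (8 higher, 7 lower), it did so for the dendritic cell list between the PBS groups (0.00557). Without replicate 3 of the day 8 AREG group it turned at day 8 for the NK and cytotoxic lymphocyte (-0.0455) and fibro-adipogenic progenitor (0.000123) lists and in the difference for the T cell (-0.0183), NK and cytotoxic lymphocyte (-0.0257) and muscle atrophy (-0.138) lists. Over the 12 arrays left out in turn these medians ranged from -0.669 to -0.0455, -0.381 to 0.000123, -0.347 to -0.0183, -0.708 to -0.0257 and -0.138 to 0.424. With both arrays out it turned for the NK (-0.0455) and fibro-adipogenic progenitor (0.000123) lists at day 8 and for the T cell (0.0626), NK (0.0172) and muscle atrophy (-0.176) lists in the difference.

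The correlation of the AREG effects across genes was 0.498 (permutation p = 0.04, adjusted 0.08 over both correlations, so it did not pass after adjustment). It was 0.381 as Spearman (permutation p = 0.08), 0.558 with the filter (permutation p = 0.06), 0.115 with both arrays out (permutation p = 0.55), and 0.224 to 0.598 leaving out 1 array. Without some single arrays the unadjusted permutation p was no longer under 0.05 (at most 0.27). Those arrays follow with the Pearson correlation, not the p, in brackets. At day 4 they were replicates 1 (0.356), 2 (0.524) and 3 (0.531) of the AREG group and 2 (0.499) and 3 (0.407) of the PBS group. At day 8 they were replicates 2 (0.476) and 3 (0.224) of the AREG group and 2 (0.468) and 3 (0.384) of the PBS group.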

Other observations

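Of what this part reports, only leaving out both arrays of the lowest quality weight, 1 of the 22 alternatives, was chosen after the results had been seen. In the heat shock and unfolded protein list single members were called in both directions with AREG. Chac1 rose at day 4 by 1.72 ± 0.32 (SE, n = 3 per group, adjusted p = 0.0198, limma) while asparagine synthetase Asns, also induced by ATF4, fell by 0.73 ± 0.13 on the log2 scale (adjusted p = 0.0198) and the chaperone Hsp90aa1 by 0.62 ± 0.12. For the mean effect Chac1 rose by 1.12 ± 0.22, and Asns (-0.64 ± 0.09), Hsp90aa1 (-0.41 ± 0.09) and the disulfide isomerase Pdia4 (-0.57 ± 0.14) fell. The heat shock and unfolded protein list as a whole did not pass at day 4 (median -0.10, 1 rose and 2 fell over all genes, 1 rose and 6 fell adjusted over the list alone). Without 1 array in turn or in another setting, the call of Chac1 at day 4 was lost in 3 of 22 alternatives.

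The muscle atrophy list did not pass at day 4, with 12 members higher and 12 lower. Runx1 (-1.10 ± 0.20), the acetylcholine receptor subunit Chrna1 (-1.10 ± 0.24), Myog and the metallothionein Mt1 (-0.81 ± 0.18) were among 5 of 24 members that fell over all genes (2 rose and 6 fell adjusted over the list alone). The median (0.03) and mean (-0.10) of the list differed in sign. In the slow fibre list (median 0.03) the calcium-binding protein Casq2 fell by 0.92 ± 0.23 on the log2 scale, in the pericyte and smooth muscle list (median 0.01) the smooth muscle actin Acta2 by 0.87 ± 0.17, in the glycolysis list (median 0.08) Pgam1 by 0.70 ± 0.18, and in the fibro-adipogenic progenitor list (median -0.09) the actin-binding protein Gsn rose by 0.48 ± 0.11.

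Lists of other cell types did not pass at day 4: tendon (median 0.25), Schwann cell and nerve (0.19), erythroid (0.18), eosinophil and mast cell (0.08), dendritic cell (-0.08), keratinocyte (-0.03), B cell (-0.02) and the ligands and receptors of the EGF family (-0.05). In the sex-linked list (median -0.01) Xist lay between 4.49 and 5.06 log2 units and the Y-linked genes Eif2s3y, Kdm5d and Uty between 8.72 and 9.38, 7.45 and 8.13, and 8.50 and 9.01 in all 12 arrays. Between the PBS groups the slow myosin light chain Myl2 rose by 1.46 ± 0.28, and Erbb3 fell by 0.97 ± 0.14 on the log2 scale (adjusted p = 0.00108, limma).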
